A study of Mus musculus with 6 samples.

How the data were processed

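Total RNA from aortas of 32-week-old mice was profiled on 6 single-colour oligonucleotide arrays, 3 from wild-type C57BL/6J mice and 3 from apoE-/- mice on the same background. The labels give a genotype, an age and a replicate number, and do not say whether replicates came from single animals, pools or repeat preparations of one pool, so p-values measure only the spread between these samples, which may be technical. The deposited table holds 1 intensity per probe set and array for 45101 probe sets, on a linear scale. The software that made these intensities, its version and the scan settings are not given in the sources used here. Tested on the values, every array had a mean intensity of 500.002 after trimming 2% of the probe sets at each end, so the deposited intensities had been scaled by the authors to one common level. The table holds no detection calls, and no call of presence or absence was made here.

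Gene names came from the platform annotation of these arrays (Affymetrix Mouse Genome arrays), which can be old and listed 35890 of the probe sets. Of these, 34958 carried 1 gene symbol and 932 carried several, which were not used to name a gene. A further 9160 probe sets, control probe sets aside, had no entry. Symbols were updated through the gene identifiers of the GRCm38.p6 gene table, in which 34754 of the probe sets with 1 symbol were found. That table was used for names and for which genes neighbour each other, and no coordinates are given because the array table names no genome build.

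Intensities were transformed to log2(intensity + 16), which compresses changes of dim probe sets, so a fold change on this scale understates the change of a gene with low intensity. The deposited scaling was kept because array medians, from 178 to 195.5, differed by less than 1.5 times. The 64 control probe sets were left out, as was the lower 40% of the remaining probe sets by mean over all 6 arrays (18015 of them), which left 27022. Each gene was represented by the kept probe set of highest mean over all arrays, giving 13031 genes. Other probe sets of a gene were compared in sign: 202 of the called genes had several kept probe sets, and in 181 all of them changed in the same direction.

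The 2 genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with genotype as the only term, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p for a gene below is from this fit. With 3 arrays against 3, an exact permutation test of one gene cannot give a two-sided p below 0.1, so none is given. Run on simulated arrays with the means and spread of these 13031 genes, the fit recovered 88% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, with 10 false calls among 197. The simulated noise was normal, independent between genes and equal in both genotypes, with the spread that the fit itself had estimated. It lacked the shared deviations of genes on the real arrays, so these rates check the fit and do not carry over to the data. Precision is limited by the number of arrays.

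Before the data were examined, 37 gene lists were written down for the cell types and pathways of the vessel wall, for plaque and lipid biology and for other tissues that an aorta sample could hold. Each was tested against the other genes with limma's camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. A repeat with the correlation estimated from the residuals called 0 of the 37 lists, 12 of which had an unadjusted p under 0.05 there. That version rests on the few residual degrees of freedom of 6 arrays, and its adjusted p is printed beside each list that the preset version called. Several lists share members with the macrophage list, as stated where it matters.

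The genes named below follow a rule fixed in advance: Apoe, the 12 largest rises and 12 largest falls among called genes whose 3 apoE-/- values all lay on one side of the 3 wild-type values, and up to 4 called members of each list by size of change, or the member with the smallest p where none was called. Genes named outside it are said to be. Genes whose start lies within 10 Mb of Apoe were compared with genes on other chromosomes by Fisher's exact test, two-sided, with Apoe itself left out.

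Arrays were checked for batches with the 3′ to 5′ ratio of control probe sets and pairwise correlations; the labels give no batch or date. Alternatives tried were other log offsets (1 and 64), quantile normalization, median centring, no filter and a 60% filter, no intensity trend, array weights, the median of a gene's probe sets, a replicate block, a 2-fold minimum, an ordinary two-sample test, and leaving out each array in turn.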

Results

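The series addressed how gene expression in the aorta of mice lacking apolipoprotein E, a strain that develops high plasma cholesterol and atherosclerotic plaques, differs from that of wild-type mice at 32 weeks of age. Each genotype was represented by 3 arrays. Median intensity per array lay between 178 and 195.5 units, and between 33.5% and 36.0% of probe sets were under 100 units. Pairs of arrays of the same genotype correlated at r = 0.966 to 0.972 over all probe sets (6 pairs) and pairs of different genotype at r = 0.950 to 0.968 (9 pairs), so no 2 arrays were copies of one another. The first principal component held 50.4% of the variance and separated the genotypes. The apoE-/- replicate 2 array, at 9.77 on that component, lay nearer to the wild-type arrays, which lay between -24.9 and -18.8, than the other apoE-/- arrays did, at 24.4 and 33.4. The 3′ to 5′ ratio of the beta-actin control was 1.15 to 1.16 on the apoE-/- arrays and 1.16 to 1.21 on the wild-type arrays without overlap, whereas the Gapdh ratio overlapped (0.705 to 0.816 against 0.736 to 0.775).

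Apoe, the disrupted gene, was read first as a check of the labels. Its single probe set gave 5207 ± 778 units (SD, n = 3) in wild-type aorta and 253 ± 203 units (SD, n = 3) in apoE-/- aorta, a log2 change of -4.65 ± 0.56 (SE, limma adjusted p = 0.0037). The 3 apoE-/- arrays read 239.5, 56.3 and 462.1 units, each far under the lowest wild-type array at 4309 units. The labels of all 6 arrays matched their Apoe signal. Whether the probe set lies in the part of the gene removed by targeting is not known from the table.

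Of 13031 genes tested, 410 rose and 63 fell in apoE-/- aorta, and 246 of the rises but only 8 of the falls were at least 2-fold. All 473 called genes had 3 apoE-/- values on one side of the 3 wild-type values. Among all genes tested 24.6% had groups that did not overlap, against the 10% that chance gives for 3 against 3. Changes over all genes leaned slightly lower, with a median log2 change of -0.05 and 5356 of 13031 positive. Medians and signs of the gene lists below are not corrected for this. On this log2 scale the largest rise was that of Mmp12, macrophage elastase, from 34.5 ± 26.7 to 5738 ± 2140 units (SD, n = 3), a log2 change of 6.88 ± 0.39 (SE). Cd5l, a protein secreted by macrophages, rose from 201 ± 25.6 to 8563 ± 1857 units, and Gpnmb, a glycoprotein of lipid-laden macrophages, from 787 ± 72.9 to 9909 ± 2051 units. Trem2, a lipid-sensing receptor of macrophages, rose by 4.11 ± 0.31 in log2, and Atp6v0d2, a subunit of the vacuolar proton pump, by 4.07 ± 0.31. Lcn2 (lipocalin 2) rose by 4.87 ± 0.35, Bex1 by 4.60 ± 0.57, Slc15a3, a lysosomal peptide transporter, by 4.15 ± 0.39, Rnf128, a ubiquitin ligase, by 3.78 ± 0.38, and Wfdc17 by 3.46 ± 0.26. The collagenase Mmp13 rose by 4.44 ± 0.85, with 1275 ± 1028 units in apoE-/- against 22.6 ± 13.4 in wild type, and Col2a1, the collagen of cartilage, by 3.49 ± 0.47. Wild-type means of Mmp12, Mmp13, Trem2, Slc15a3 and Bex1 were between 22.6 and 54.1 units and are not shown to be above background, so the sizes and ranks of these rises depend on the log offset. The Mmp12 log2 fold change was 7.53 with an offset of 1 and 5.84 with 64, and all 5 genes were called with both. The adjusted p-values of these 12 genes lay between 4.14e-06 for Cd5l and 0.0264 for Mmp13.

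**Figure D1:**
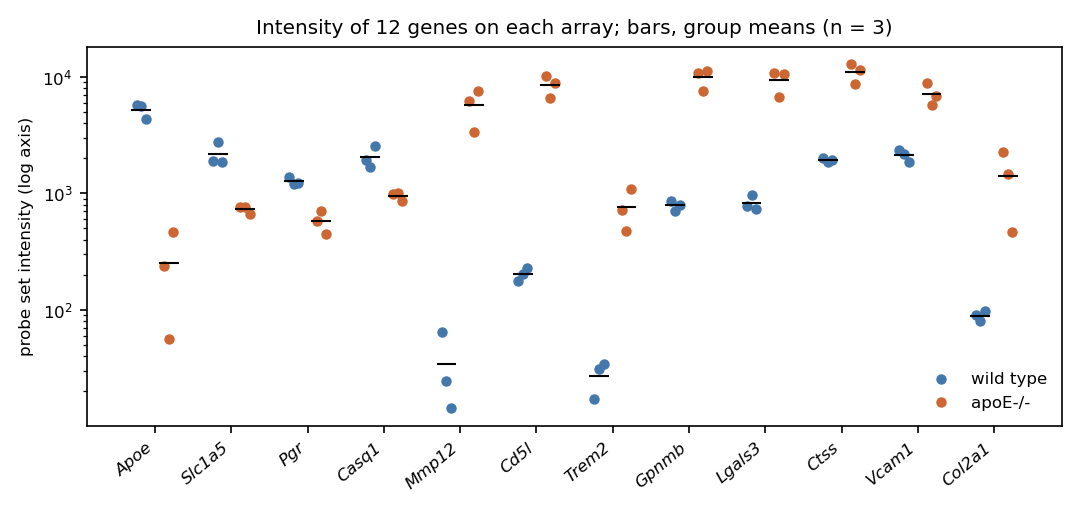
Probe set intensity (log axis) of 12 genes on each of the 3 wild-type (blue) and 3 apoE-/- (orange) arrays, with bars at the group means. Apoe, Slc1a5, Pgr and Casq1 were lower on all 3 apoE-/- arrays than on any wild-type array, and the other 8 genes were higher.

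After Apoe, the falls were smaller than the leading rises. Bves, a membrane protein of muscle, fell by 1.54 ± 0.25 on the log2 scale (SE), from 367 ± 30.8 to 121 ± 48.6 units (SD, n = 3). Slc1a5, a glutamine transporter, fell by 1.53 ± 0.16, from 2170 ± 515 to 732 ± 53.9 units. A further Slc1a5 probe set had a log2 change of only -0.30. The transcription factors Atoh8 and Zbtb16 had log2 changes of -1.52 ± 0.31 and -1.34 ± 0.25, the galectin Lgals4 of -1.31 ± 0.23 and the progesterone receptor Pgr of -1.13 ± 0.16. Casq1, the calcium store protein of muscle, fell by 1.08 ± 0.15, and the log2 changes of Wdr77 and Nudt19 were -0.99 ± 0.12 and -0.97 ± 0.10. The heat shock gene Hspa1a changed by -0.89 ± 0.19 and the receptor Tnfrsf12a by -0.88 ± 0.18. Adjusted p-values of these 11 genes lay between 0.00167 for Nudt19 and 0.0444 for Hspa1a. Hspa1a has a near-identical copy, Hspa1b, whose signal its probes can share, so which copy fell is uncertain. Slc1a5 and Lgals4 lie within 10 Mb of Apoe, among the neighbours described below, for which probe mismatches stay open.

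The number of called genes depended on single arrays. It was 267 without wild type replicate 1, 309 without wild type replicate 2, 233 without wild type replicate 3, 153 without apoE-/- replicate 1, 194 without apoE-/- replicate 3, and 686 without apoE-/- replicate 2. An ordinary two-sample test of each gene called 0 genes after Benjamini-Hochberg adjustment, with a lowest adjusted p of 0.103 and 2069 genes at an unadjusted p under 0.05, where limma had 2394.

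Genes of macrophages and foam cells, the lipid-filled macrophages of plaques, rose almost throughout. Of 35 listed genes tested, 32 rose and none fell, and 34 rose when adjusted over the list alone. The median log2 change of the list was 2.03. Besides Trem2, Atp6v0d2 and Gpnmb, the lectin Lgals3 rose from 828 ± 129 to 9391 ± 2326 units (SD, n = 3, log2 change 3.46 ± 0.19). Leaving out any single array left between 26 and 33 members called. In camera the list stood above the other genes (adjusted p = 1.48e-52, and adjusted p = 0.146 with an estimated correlation).

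Antigen presentation, complement and interferon response genes were called higher as 3 lists, with 6 of 10, 5 of 14 and 4 of 21 members passing the test (adjusted p = 0.146 for each list with an estimated correlation). Of 10 genes of MHC class II presentation, 6 rose (7 adjusted over the list alone). They were 5 genes outside the macrophage list and Ctss, the cathepsin that processes the invariant chain, which is in both lists. Ctss rose from 1934 ± 78.5 to 11060 ± 2093 units (SD, n = 3), Cd74, the invariant chain, by 1.43 ± 0.17 in log2 (SE), and the class II chains H2-Eb1 by 1.33 ± 0.15 and H2-Ab1 by 1.13 ± 0.12. Of 14 complement genes, 5 rose (9 over the list alone), among them the receptor C3ar1 by 2.59 ± 0.28 and the first-component chains C1qc, C1qb and C1qa by 2.17 ± 0.21, 2.04 ± 0.18 and 1.86 ± 0.15, of which the 3 chains also stand in the macrophage list. Of 21 genes of MHC class I and the interferon response, 4 rose (15 over the list alone), namely Ifit1 (1.01 ± 0.16), Oasl2 (0.96 ± 0.15), Ifit3 (0.79 ± 0.13) and the immunoproteasome subunit Psmb8 (0.79 ± 0.16). For this last list no member was called without apoE-/- replicate 1, 1 without wild type replicate 3 and 2 without apoE-/- replicate 3, and 8 complement genes were called without apoE-/- replicate 2. The largest camera adjusted p of the 3 lists was 1.13e-09.

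Chemokines, cytokines and adhesion molecules, and lipid mediator genes were called higher as 3 lists, with 10 of 20, 10 of 18 and 4 of 15 members passing the test (adjusted p = 0.146 for each list with an estimated correlation). Of 20 inflammatory chemokines and receptors, 10 rose (17 over the list alone), among them Ccl2, which attracts monocytes, by 2.62 ± 0.46 in log2 (SE), Ccl8 by 2.17 ± 0.30, the receptor Cxcr4 by 2.06 ± 0.35 and Ccl6 by 1.88 ± 0.26. Of 18 cytokines and adhesion molecules, 10 rose (13 over the list alone). Vcam1, which captures leukocytes on endothelium, rose from 2128 ± 244 to 7156 ± 1590 units (SD, n = 3), the interleukin 1 antagonist Il1rn by 1.75 ± 0.29, Tlr1 by 1.62 ± 0.35 and cyclooxygenase 2 (Ptgs2) by 1.51 ± 0.16. Of 15 genes of leukotriene and prostanoid synthesis, 4 rose (7 over the list alone), which were Pla2g7 (2.46 ± 0.52), a phospholipase carried on lipoproteins, Ptgs2, Hpgds (1.33 ± 0.28) and Alox5ap (1.01 ± 0.15), the activator of 5-lipoxygenase. The largest camera adjusted p of the 3 lists was 8.49e-04. The cytokine list had 3 called members without apoE-/- replicate 1 and 5 without apoE-/- replicate 3. The chemokine list had 5 called members without apoE-/- replicate 1, and the leukotriene list 1 without that array, 2 without apoE-/- replicate 3 and 2 without wild type replicate 3.

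Lysosomal, oxidant and lipid efflux genes rose in part. Of 25 lysosomal genes, 10 rose (19 over the list alone), which were 9 outside the macrophage list and Ctss, which is in both. After Ctss the largest rises were those of the protease Lgmn (1.69 ± 0.19 in log2, SE), Gusb (1.62 ± 0.21) and acid lipase Lipa (1.54 ± 0.24), which frees cholesterol from its esters. Of 21 genes of oxidative stress and the NADPH oxidase, 6 rose (9 over the list alone); 5 of them encode or regulate the phagocyte oxidase, including Cybb (2.01 ± 0.17), Rac2 (1.52 ± 0.23) and Ncf4 (1.37 ± 0.28), and the other was haem oxygenase Hmox1 (2.46 ± 0.41). Of 16 genes of cholesterol efflux and LXR targets, 7 rose (8 over the list alone), among them Cd5l, the esterase Nceh1 (2.48 ± 0.32), the exporter Abcg1 (1.85 ± 0.19) and Lipa. Adjusted p-values with an estimated correlation were 0.146, 0.146 and 0.175 for these lists, against 1.25e-18, 5.10e-07 and 2.65e-06 with the preset one. Without wild type replicate 1, wild type replicate 3, apoE-/- replicate 1 or apoE-/- replicate 3, the lysosomal list had 6, 5, 6 and 6 called members and the oxidant list 3, 3, 2 and 3. The efflux list had 4 without apoE-/- replicate 1.

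Matrix genes changed unevenly. Of 20 metalloproteinases and inhibitors, 6 rose (9 over the list alone), with Mmp12, Mmp13, the inhibitor Timp1 (2.39 ± 0.24 in log2, SE) and Adam8 (2.26 ± 0.28) in front (camera adjusted p = 5.45e-07, and adjusted p = 0.146 with an estimated correlation). Of 26 collagen and matrix genes only 4 rose (7 over the list alone, with 1 lower): Col8a1, from 603 ± 75.4 to 2321 ± 281 units (SD, n = 3), Thbs1 by 1.81 ± 0.15, the keratan sulfate proteoglycan Lum by 1.02 ± 0.14 and Col12a1 by 0.78 ± 0.17. The camera call of that list (adjusted p = 1.61e-04) had adjusted p = 0.40 with an estimated correlation. Of 16 osteochondrogenic genes, 3 rose (4 over the list alone), which were Col2a1, the decoy receptor Tnfrsf11b (1.54 ± 0.13) and Sox9 (1.09 ± 0.24), the transcription factor of cartilage. Its adjusted p = 0.264 with an estimated correlation, against 3.56e-04. Of 18 proliferation genes, 4 rose (8 over the list alone) from low levels, namely Mki67 (101 ± 19.6 to 314 ± 93.1 units), Top2a (1.23 ± 0.15), Birc5 (1.09 ± 0.22) and Rrm2 (1.01 ± 0.17), with adjusted p = 1.14e-08 and adjusted p = 0.146 with an estimated correlation. Only 1 proliferation gene was called without apoE-/- replicate 1 and 1 without apoE-/- replicate 3.

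**Figure D2:**
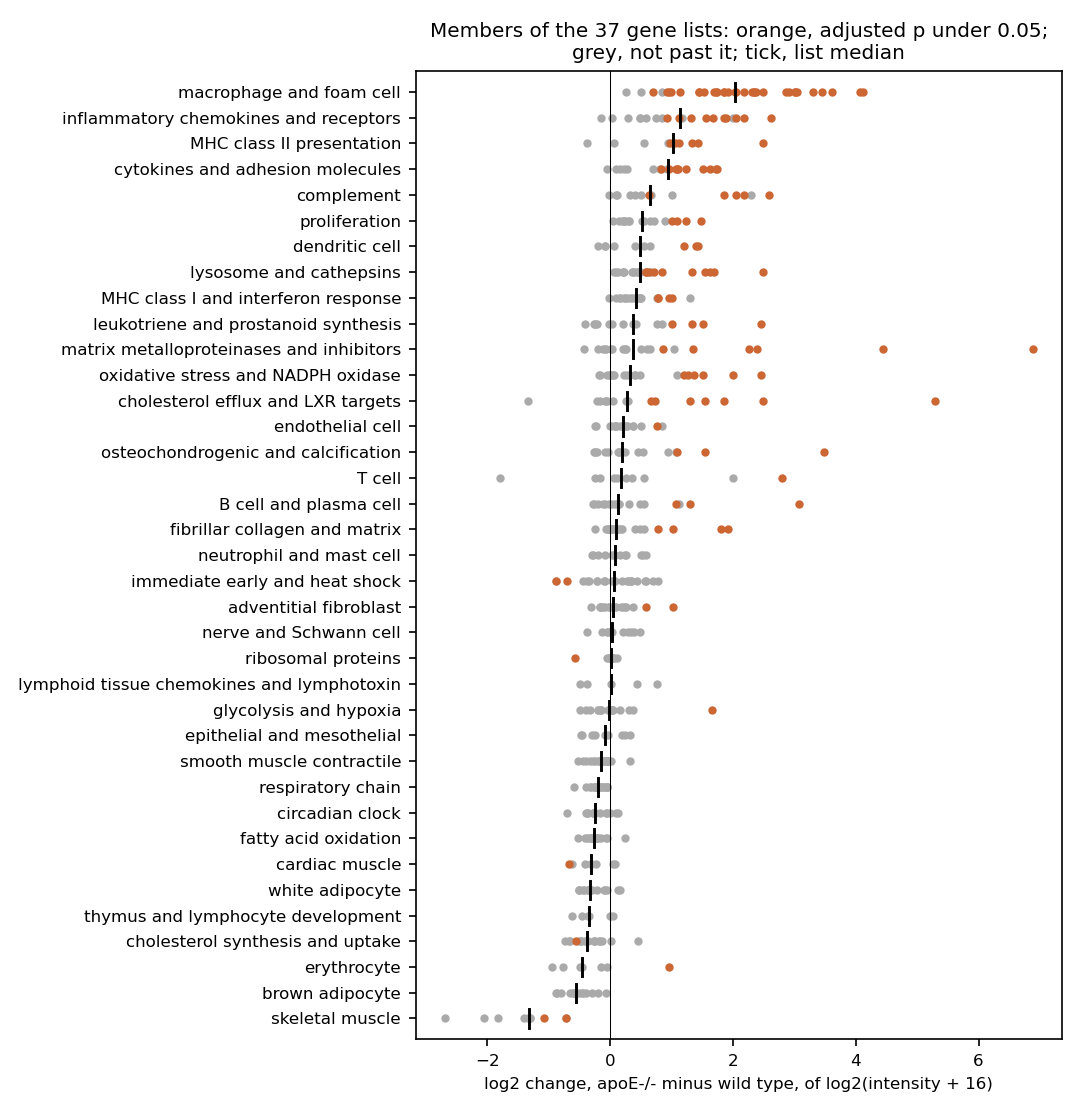
Log2 change of each tested member of the 37 gene lists (apoE-/- minus wild type, log2(intensity + 16) scale), with called members in orange, the others in grey and a tick at each list's median. The macrophage list has the highest median, 2.03, and the skeletal muscle list the lowest, -1.32.

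Lymphocyte lists held few called genes. Of 18 B cell and plasma cell genes, 3 rose, both over all genes and over the list alone: Cd72 (3.08 ± 0.22 in log2, SE), Cd22 (1.30 ± 0.21) and Sdc1 (1.08 ± 0.15). Cd72 and Sdc1 are also made by cells other than B cells, and the core B cell gene Cd79a, named after its value was seen, had a log2 change of 0.03 (adjusted p = 0.964). Members not called went both ways, from Ighm (1.13 ± 0.45, adjusted p = 0.231) to Igha (-0.27 ± 0.19, adjusted p = 0.507), also named after their values were seen. The camera call of that list (adjusted p = 0.00925) had adjusted p = 0.443 with an estimated correlation, 0.168 without apoE-/- replicate 3 and 0.109 without wild type replicate 2. Of 10 T cell genes above the filter, 1 rose over all genes and over the list alone, the interleukin 7 receptor Il7r (2.81 ± 0.32), which is not restricted to T cells. Its uncalled members, also named after their values were seen, ranged from Ccl5 (2.01 ± 0.74, adjusted p = 0.199) to Zap70 (-1.80 ± 0.55, adjusted p = 0.133). The list was not called (adjusted p = 0.151), and the rest of its 25 genes were not tested, being under the filter or without a named probe set. Of 10 dendritic cell genes, 3 rose over all genes and over the list alone, Irf8 (1.43 ± 0.23), Cd83 (1.41 ± 0.25) and Fscn1 (1.20 ± 0.18), with adjusted p = 9.39e-04 and adjusted p = 0.146 with an estimated correlation. No member was called without apoE-/- replicate 1, and 1 without wild type replicate 3. The 7 others, named after their values were seen, lay between -0.20 (Flt3) and 0.65 (Cd209a), with Zbtb46 and Siglech at -0.08 each and Batf3 at 0.56. In bulk tissue the 3 rises do not show that dendritic cells increased. Lymphoid tissue chemokines and lymphotoxin genes (5 of 14 testable) and genes of neutrophils and mast cells (13) held no called member. The members with the smallest p were Tnfsf13b (0.44 ± 0.14, adjusted p = 0.145) and Mmp8 (0.51 ± 0.16, adjusted p = 0.152). Over the list alone, 2 of the lymphoid tissue genes passed.

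Contractile genes of smooth muscle, the main cell type of the aortic wall, changed little one by one. None of 23 passed, over all genes or over the list alone; Smtn had the smallest p (7361 ± 87.1 against 5867 ± 461 units, SD, n = 3, adjusted p = 0.0858). Their median log2 change was -0.14, against -0.05 over all genes tested, and 2 of 23 were positive. Without apoE-/- replicate 2, 2 members were called, and 1 without wild type replicate 3. Camera placed the list below other genes (adjusted p = 0.00468), with adjusted p = 0.443 with an estimated correlation and 0.0817 without apoE-/- replicate 3, where the median was -0.08. Of 21 endothelial genes, 1 rose over all genes and over the list alone, Emcn (0.76 ± 0.16 in log2, SE), and the list median was 0.22; its camera call (adjusted p = 4.85e-04) had adjusted p = 0.411 with an estimated correlation and 0.0676 without wild type replicate 3, where the median was 0.13; Emcn was not called without wild type replicate 1, wild type replicate 3, apoE-/- replicate 1 or apoE-/- replicate 3. Of 18 genes of adventitial fibroblasts, 2 rose over all genes and over the list alone, Lum and Efemp1 (0.59 ± 0.12), and the list was not called (adjusted p = 0.0714), but it was without wild type replicate 1 (0.0150), apoE-/- replicate 2 (0.0495) and apoE-/- replicate 3 (0.0274). Only Lum was called without wild type replicate 2, wild type replicate 3, apoE-/- replicate 1 or apoE-/- replicate 3. Beside these wall cell lists, the beta-actin 3′ to 5′ ratio separated the genotypes (1.15 to 1.16 in apoE-/-, 1.16 to 1.21 in wild type).

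Skeletal muscle and brown adipocyte genes were called lower as lists, with 2 of 10 and none of 16 members passing the test (adjusted p = 0.40 for each list with an estimated correlation), and single wild-type arrays set a large part of both medians. Of 10 skeletal muscle genes, 2 fell over all genes and over the list alone, Casq1 and creatine kinase Ckm (log2 changes of -1.08 ± 0.15 and -0.71 ± 0.13, SE). Ckm also lies within 10 Mb of Apoe, among the neighbours described below. The wild type replicate 3 array read 7 of the 10 at more than 3 times the highest other array, as for Acta1 at 6440 units against 329. The called genes Casq1 and Ckm were not among these 7, at 1.33 and 0.97 times the highest other array on that array. This holds for the Ckm probe set that represented the gene. A further Ckm probe set had a larger log2 change of -2.59 and was not compared array by array, so an excess of Ckm on that array is not excluded. The list's median was -1.32 with that array and -0.40 without it, and -2.03 and -2.01 without wild type replicates 1 and 2. Leaving out any array but apoE-/- replicate 2 left 1 called member, Casq1. Its camera adjusted p was 2.91e-04. None of 16 brown adipocyte genes passed, over all genes or the list alone, and all had negative changes, with a median of -0.56 that became -0.26 without wild type replicate 2. Fabp3 had the smallest p (-0.56 ± 0.17, adjusted p = 0.126). Without wild type replicate 1 the Fabp3 log2 fold change was -0.77 and was called (adjusted p = 0.0171), and the list median was -0.75. Camera gave this list an adjusted p of 2.19e-04. None of 21 respiratory chain and 17 fatty acid oxidation genes passed either, and their camera calls (adjusted p = 0.00826 and 0.0425) had adjusted p = 0.61 and 0.659 with an estimated correlation, and 0.830 and 0.845 without wild type replicate 2. Without apoE-/- replicate 2 they were 0.151 and 0.338, and the fatty acid oxidation list had 0.112 without apoE-/- replicate 3. Their members with the smallest p were Uqcrc1 (-0.58 ± 0.19, adjusted p = 0.157) and Eci1 (-0.52 ± 0.28, adjusted p = 0.374). Among 9 cardiac muscle genes 1 fell (2 over the list alone), the calcium release channel Ryr2 (log2 change -0.68 ± 0.15, SE, adjusted p = 0.0498); the list's adjusted p was 0.0213, with adjusted p = 0.356 with an estimated correlation and 0.0760 without wild type replicate 2. Ryr2 was called with only 1 of the arrays left out, apoE-/- replicate 2. The white adipocyte list was not called (adjusted p = 0.0765; Retn -0.51 ± 0.20, adjusted p = 0.229), but it was without wild type replicate 1 (1.30e-04), wild type replicate 3 (0.00880) and apoE-/- replicate 1 (0.00298).

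**Figure D3:**
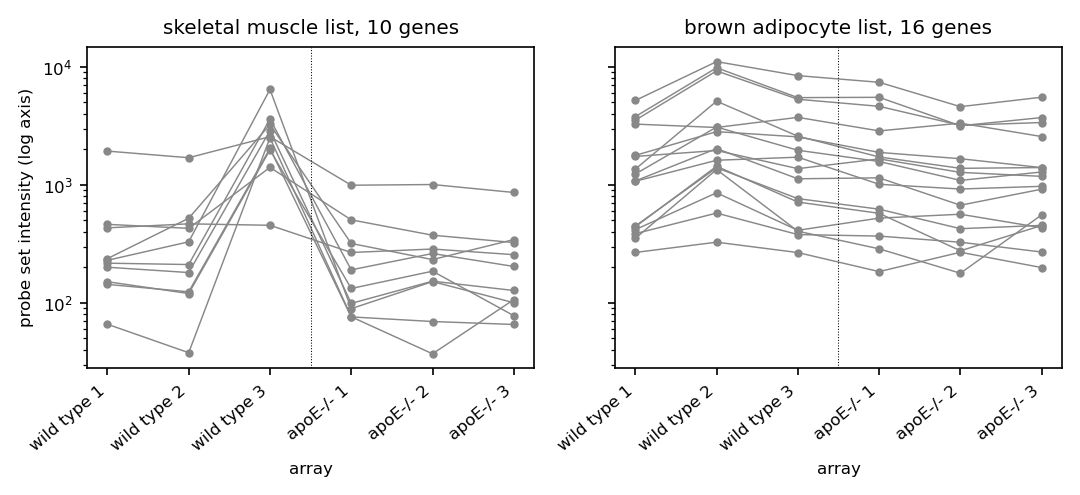
Probe set intensity (log axis) of the 10 tested skeletal muscle genes (left) and 16 brown adipocyte genes (right) on each array, with 1 line per gene. Wild type replicate 3 stands apart for 7 of the skeletal muscle genes, and wild type replicate 2 lies above the other arrays for most brown adipocyte genes.

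Genes of cholesterol synthesis and uptake were called lower as a list (camera adjusted p = 2.19e-04, and adjusted p = 0.356 with an estimated correlation). Of 18 tested, 1 fell over all genes and over the list alone, the sterol oxidase Msmo1 (log2 change -0.55 ± 0.12, SE, adjusted p = 0.0444), and 16 of 18 had a negative change, with a median of -0.38. Msmo1 was not called with any 1 array left out. Among lists that camera did not call, heat shock genes Hspa1a and Hsph1 (-0.71 ± 0.13) fell in the immediate early and heat shock list (2 of 24 over all genes, 3 over the list alone), the transferrin receptor Tfrc (0.96 ± 0.19) rose in the erythrocyte list, hexokinase Hk3 (1.67 ± 0.21), an isoform of leukocytes, rose in the glycolysis and hypoxia list, and Rps6 fell by 0.57 ± 0.12 among 12 ribosomal proteins; of these, Tfrc was called only without apoE-/- replicate 2, Rps6 in no set of 5 arrays, Hsph1 only without wild type replicate 3, and Hspa1a only without apoE-/- replicate 2. The erythrocyte list had 1 further, lower, member over the list alone, and the glycolysis and ribosomal lists none. The medians and means of the last 2 lists differed in sign (-0.02 and 0.03 for glycolysis, 0.02 and -0.03 for ribosomal proteins). No member was called in the nerve, thymus, epithelial or circadian lists, whose smallest p-values belonged to Dbh (0.40 ± 0.18, adjusted p = 0.278), Satb1 (-0.63 ± 0.21, adjusted p = 0.159), Upk1b (-0.46 ± 0.17, adjusted p = 0.190) and Per2 (-0.69 ± 0.27, adjusted p = 0.227). The thymus list was called without wild type replicate 2 (0.0329) and the circadian list without wild type replicate 3 (0.0165).

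A targeted allele is bred into a strain together with the DNA around it, and the neighbours of Apoe on chromosome 7 were therefore compared with genes elsewhere. Within 10 Mb of Apoe, 11 of 193 genes (5.70%) were called, against 429 of 11946 genes (3.59%) on other chromosomes, an odds ratio of 1.62 (95% interval 0.79 to 3.002, Fisher's exact test, two-sided, p = 0.119). Without apoE-/- replicate 1 the odds ratio for genes near Apoe was 2.75 (exact p = 0.0274). By direction, which was looked at only after the data were examined, 7 of the 193 had fallen (3.63%, against 0.410% elsewhere; odds ratio 9.13, interval 3.44 to 20.6, Fisher's exact test, two-sided, p = 2.76e-05) and 4 had risen (2.07% against 3.18%, odds ratio 0.64, exact p = 0.532). The 7 genes, named after their values were seen, were Inafm1, Slc1a5, Ckm, the surface glycoprotein Bcam, the mitochondrial ribosomal gene Mrps12, Lgals4 and the myosin phosphatase inhibitor Ppp1r14a, with log2 changes of -0.71, -1.53, -0.71, -0.81, -0.85, -1.31 and -0.83.

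**Figure D4:**
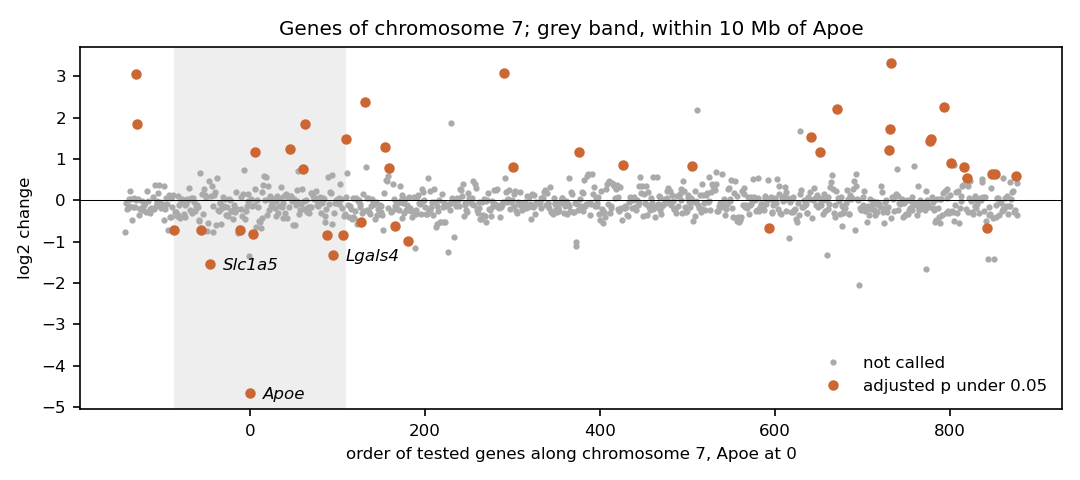
Log2 change (apoE-/- minus wild type) of the tested genes of chromosome 7 in their order along it, with Apoe at 0, called genes in orange and a grey band over the genes within 10 Mb. Besides Apoe, 7 called genes in the band are below 0 and 4 are above.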

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

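Probe sets without a gene name here were outside the comparison of named genes and were tested apart from it with the same limma fit. Of 3686 such probe sets above the filter, 24 were higher and 1 was lower in apoE-/- aorta at an adjusted p under 0.05, and it is this signal in data not otherwise described that singled them out. The largest change was that of probe set 1449254_at, from 99.8 ± 15.4 units in wild type to 11942 ± 1722 in apoE-/- (SD, n = 3; log2 change 6.69 ± 0.15, SE, adjusted p = 1.51e-09). The next was 1445626_at, with a log2 change of 2.97 ± 0.31, and the 1 that fell was 1436853_a_at, from 763.5 ± 172 to 369.5 ± 70.5 units.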

How the results depend on the processing

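Apart from Apoe, 95 genes were named by the rule fixed in advance, and their direction held under every alternative in which they could be fitted; genes named outside that rule were not followed through the alternatives. Of these genes, 84 had been called and 11 had not, and the ordinary two-sample test ended all 84 calls. Leaving out one array ended 8 (apoE-/- replicate 2) to 34 (apoE-/- replicate 1), no filter and no intensity trend 18 each, the replicate block 13, and the other alternatives 8 or fewer. The 2-fold minimum is left out of these counts, since by construction it ends the call of every gene that changed less than 2-fold. The 410 higher genes stayed within 1.5 times of that count under changes of offset, scaling, filter, trend, weights and probe set rule, but which genes were called changed more. Under these settings, the calls shared with the 473 ranged from 296 with no intensity trend and 317 with no filter to 453 after quantile normalization and 472 with array weights. The replicate block shared 284, and leaving out one array shared 149 (apoE-/- replicate 1) to 426 (apoE-/- replicate 2). The 63 lower genes were 31 with no intensity trend and 121 with array weights. At least 2-fold changes numbered 246 higher and 8 lower, by construction of the threshold. The ordinary test called 0 higher and 0 lower (limma: 2394 genes at an unadjusted p under 0.05; ordinary test: 2069), and under it Apoe kept its log2 change of -4.65 with an adjusted p of 0.198, against 0.0037. Leaving out one array gave 143 to 534 higher and 10 to 152 lower genes, with fewer arrays and, for apoE-/- replicate 2, the array with the mildest difference removed; the cause was not tested. Replicate numbers did not mark related arrays, since deviations from the group means of same-numbered arrays correlated at -0.10, -0.18 and -0.05 and none of the arrays correlated best with its own number (the highest values, 0.21 and 0.19, were between arrays of different number); the fit with a replicate block called 283 higher and 18 lower genes, with fewer residual degrees of freedom. With an estimated correlation camera called 0 lists higher and 0 lower, in place of 17 and 7, with 12 at an unadjusted p under 0.05; the other settings called 16 to 18 higher and 5 to 9 lower. In camera's direction some uncalled lists turned, namely ribosomal proteins after quantile normalization (median log2 change 0.0055) and epithelial genes without a filter (0.115). With one array left out, lists that turned at least once had medians of -0.105 to -0.031 (glycolysis and hypoxia), -0.063 to 0.058 (ribosomal proteins), -0.194 to 0.059 (epithelial and mesothelial), -0.521 to 0.031 (white adipocyte) and -0.468 to -0.036 (fatty acid oxidation, the only called one, which turned without wild type replicate 2, adjusted p 0.845). The odds ratio for genes near Apoe, 1.62 and not past the threshold, passed it with a window of 20 Mb (1.79), after median centring (2.21), with a 60% filter (1.996) and without apoE-/- replicate 1 (2.75; 1.49 to 2.75 over the arrays left out), was 9.13 for lower genes alone and 0.64 for higher genes alone; the cause was not tested. Settings for that result were chosen after seeing the data, as was the ordinary test of single genes. The number of arrays and the missing detection calls limit what can be said of dim genes.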

Other observations

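Tests of dilution and of the macrophage subsets below were chosen after the results they bear on were seen, as were the windows elsewhere in the genome, the restriction to falls near Apoe, the correlations of other lists and the bootstrap interval of the glucocorticoid genes; genes named here outside the report were chosen after their values were seen. Genes of lipid-associated macrophages, the plaque cells that take up and store lipid, were compared with genes of the macrophages resident in healthy vessel walls. Of 16 genes of the first list tested, 13 rose, with Fabp5, a fatty acid binding protein, going from 1989 ± 1076 to 10185 ± 2324 units (SD, n = 3) and the actin-capping gene Capg by 1.46 ± 0.17 in log2 (SE, limma adjusted p = 0.0035). Of 18 resident genes 3 rose, namely Mrc1 (0.70 ± 0.13, adjusted p = 0.022), Folr2 (0.82 ± 0.16, adjusted p = 0.026) and Ccl8 (2.17 ± 0.30); 1 was called without wild type replicate 2, wild type replicate 3, apoE-/- replicate 1 or apoE-/- replicate 3. The resident list as a whole was also called higher, with 16 of 18 changes positive (camera adjusted p = 1.52e-04, and adjusted p = 0.0393 with an estimated correlation, both over only the 3 lists added after the data were seen and not comparable with the adjustment over 37 lists). Among its genes that were not called, changes lay between those of Csf1r (0.50 ± 0.14, adjusted p = 0.0999) and Cbr2 (-0.20 ± 0.10, adjusted p = 0.325). The mean log2 change was 2.21 for the first list and 0.32 for the second, a difference of 1.89 against a pooled SD between arrays of 0.22, and the difference of list means was higher on all 3 apoE-/- arrays than on any wild-type array. Without the 12 largest rises named in the report the difference was 1.07. These values are consistent with a larger rise of lipid-associated than of resident macrophage genes, both of which were higher, a hypothesis found on the same data and on bulk tissue, in which other cells also make several of these genes.

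Zbtb16 and Usp2, both known to respond to glucocorticoids, fell, and it was asked whether other glucocorticoid-responsive genes fell with them. Of 18 others, none was called over all genes, 8 were positive and camera gave an unadjusted p of 0.895. The median log2 change was -0.099 (95% bootstrap interval -0.38 to 0.32), which lies just above the -0.1 that had been set as the bound against a joint fall, but not by more than its spread. Klf15 (-0.76 ± 0.17, adjusted p = 0.0514) and Ddit4 (1.10 ± 0.25, adjusted p = 0.0555) lay in opposite directions, so the set does not settle the question. With Zbtb16 and Usp2 included, the list of 20 genes was not called on all arrays (camera adjusted p = 0.450 over the 3 added lists). Over the list alone, 5 members were lower and 2 higher. It was called lower only without wild type replicate 3 (median -0.28, camera adjusted p = 0.0407 over the 3 added lists). Its members called over all genes, 2 in all, were 0 without apoE-/- replicate 1 and 1 without wild type replicate 3 or apoE-/- replicate 3.

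Genes near Apoe were called lower more often than genes elsewhere, with an odds ratio of 9.13 against other chromosomes that is itself the pattern noticed and not a separate test of it. It lay between 5.60 and 37.6 in 16 alternative settings and arrays left out, and against the rest of chromosome 7 it was 5.14 (exact p = 0.00480), or 4.63 with a window of 5 Mb (exact p = 0.0235). Of 11762 windows of the same width around genes on other chromosomes with at least 30 tested genes, none held 7 falls and the highest held 3, although 46 held as high a percentage. Windows around neighbouring genes overlap, so they are not independent, and they differ in their number of tested genes, for which only the percentage allows. A candidate explanation is DNA of the donor strain that stayed around the targeted allele, acting on expression or on the match to the probes. Probe mismatches stay open, since only 3 further probe sets measured called neighbours (of Ckm, Slc1a5 and Tgfb1, the last of which rose). Of these, 33.3%, that of Ckm, changed alike by at least 0.5 times the size, against 69.9% of 319 for called genes on other chromosomes. Their log2 changes were -2.59 (Ckm), -0.30 (Slc1a5) and -0.24 (Tgfb1), against -0.71, -1.53 and 1.24 for the probe sets used. The rule set no upper bound on size, and Ckm is also in the skeletal muscle list.

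Skeletal muscle and brown adipocyte genes were called lower as lists with the preset correlation (adjusted p = 0.40 for both with an estimated correlation), although no brown adipocyte gene was called. Differing amounts of adjoining muscle and brown fat on the arrays may account for this, but the test made leaves it open. Members of each list deviated together within the genotypes, with a median correlation of 0.926 for skeletal muscle and 0.709 for brown adipocyte genes, against an upper 97.5% limit of 0.277 in 1000 random lists of 12 genes. Lists that need no adjoining tissue reached like values, 0.902 for ribosomal proteins and 0.770 for macrophage genes, so moving together does not single out such tissue. That correlation takes no account of the size of the deviations, which differed. On the log2 scale, the skeletal muscle list mean was 11.2 on wild type replicate 3 and 7.64 to 8.14 on the other arrays. The means of ribosomal proteins lay between 12.98 and 13.17. For skeletal muscle the deviations were thus mainly an excess on that wild-type array. A difference between the genotypes in the fat around the aorta stays open as well, untested.

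Smooth muscle contractile genes were called lower as a list, with none of 23 members called (adjusted p = 0.443 with an estimated correlation, and 0.0817 without apoE-/- replicate 3). Dilution by infiltrating cells, which would lower endothelial genes alike, stays open. The endothelial minus smooth muscle mean was higher in apoE-/- by 0.37 in log2 with a pooled SD between arrays of 0.22, but the genotypes overlapped (-2.37 to -2.003 against -2.85 to -2.36) and the difference was 0.24 without wild type replicate 3. RNA quality stays open as well, because the mean beta-actin 3′ to 5′ ratio of apoE-/- over wild type was 0.966 without overlap, while that of Gapdh was 0.999 with overlap. A genotype effect on the cells themselves was not tested.

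As to chance, the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real split, 473 genes were called, and the highest of the others called 1. The real split called 24 lists and was again the 1 split of 10 with as many, but the highest of the others called 23. Camera with the preset correlation thus also called many lists in splits that mix the genotypes. In each of those splits, 1 side still held more apoE-/- arrays than the other. They therefore kept part of the genotype difference, and the rest of it added to the spread within the groups. Neither the gene counts nor the list counts show what chance alone would call, or whether the preset correlation calls too many lists.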
